A study of Drosophila melanogaster with 3 samples.

How the data were processed

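ChIP-seq peak lists of 3 biological replicates were used, all from whole mixed-sex Drosophila melanogaster embryos aged 0 to 24 h that express Zif (CG10267) with a C-terminal GFP. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody; the antibody field names CG10267, the tagged protein. Per the labels, a control library entered peak calling; it was not analysed here. All samples belong to 1 group, so no contrast between groups was made.

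Per the labels, relaxed peaks were called for each replicate against the control and for the pooled alignments of replicates 2 and 3, and the IDR set was derived from the lists of replicates 2 and 3 and the pooled list. The values go against this: at the 7502 IDR peaks alone in their interval and with a relaxed peak in each replicate, the pooled signal over the sum of the signals of all 3 replicates had a median of 0.991 (interquartile range 0.9698 to 1.006) and lay within 10% of 1 at 93.0% of the peaks. Over the sum of replicates 2 and 3 the median was 1.82 (1.649 to 2.014), over that of 1 and 2 it was 1.437 and over that of 1 and 3 it was 1.243. Replicate 1 was therefore not taken as independent of the pooled list or the IDR set. This comparison was added after the data were seen. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal value of each peak was taken as the peak caller's measure of enrichment over the control, an assumption since the caller is not named. It depends on the library and was not normalised between lists. The deposited −log10 q value of each peak was at its maximum of 4.41 for all 8630 IDR summits, so peaks were ranked by signal. The remaining columns used were the start, the end and the summit position, given on dm6 and printed 1-based here.

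Several properties of the lists were checked on the values. Each relaxed list held 30000 summits, with signals of 18.7 to 3759 in replicate 1 (median 47.9), 13.0 to 2495 in replicate 2 (27.1), 14.4 to 2569 in replicate 3 (37.2) and 34.1 to 8172 in the pooled list (95.3). The IDR set was the 8630 summits of highest signal in the pooled list, with the same signal values, and 480 of its intervals held more than 1 summit. The commonest width was 444 bp in replicate 1 (77.8% of peaks), 530 bp in replicate 2 (87.1%) and 510 bp in replicate 3 (80.6%). No peak lay on Y or on unplaced sequence. The median signal at the IDR peaks was 202 in replicate 1, 105 in replicate 2 and 142 in replicate 3. The lists give no read counts, so depth per replicate is unknown. Intervals are exact binomial (Clopper-Pearson, 95%) and cover counting error only; the spread between replicates is given as the SD over 3 replicates.

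Peaks were annotated with Ensembl release 115 gene models of dm6, without genes of transposable elements, on 2L, 2R, 3L, 3R, 4 and X. The gene lists, motifs, tests, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. A summit within 500 bp of an annotated TSS of any gene was called a promoter summit; the remaining summits were assigned to exon classes, introns or intergenic sequence. A protein-coding gene was called bound when an IDR summit lay within 500 bp of any of its TSSs. The rule for named genes took the 25 strongest IDR peaks within 500 bp of a protein-coding TSS that overlapped a relaxed peak in each replicate, the 5 strongest IDR peaks farther than 500 bp from any TSS, Zif and aPKC whatever their values, and up to 4 bound members of each list with the strongest peaks, of which the text gives a part. Unbound list members, where named, were added after their values were seen.

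For the replicates, the 8630 strongest peaks of each relaxed list were compared by an overlap of at least 1 bp, with 20 random placements as the chance value. The replicate signal at an IDR peak was that of the strongest overlapping relaxed peak, or 0 with none, and was divided by its median over the IDR peaks to give the relative signal. Spearman's rho was taken across peaks without a p, since peaks are not replicates. Every share by location, list or motif was also computed from the 8630 strongest peaks of each replicate alone, for its mean and SD.

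The promoter share was tested against 1000 random placements of the summits on their own chromosomes outside assembly gaps, two-sided; shares by feature used 100 placements. The 26 gene lists (1195 genes, with 2 symbols without a match and 4 matched under another spelling or name) were tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The 2 symbols were nos of the germline list, which was not counted, and ebony of the glia list, which also held this gene as e. Head-to-head promoters and X against autosomes were tested in the same way, without adjustment. The 14 motifs were scored as present or absent on either strand within 50 bp of the summit and in a 101 bp window centred 300 bp away, the side alternating by peak, and compared with a two-sided exact McNemar test, adjusted over the motifs. De novo words of 8 bases were ranked on 2L, 2R and X, the best was grown to a matrix over 5 rounds with a threshold matching 5% of the flanks, and the matrix was tested once on 3L and 3R. Signals of held-out peaks with and without a match were compared by the difference of medians in a permutation test of 100000 draws.

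Alternatives used only the 4315 strongest peaks; peaks in the strongest lists of at least 2 replicates; peaks shared by the strongest lists of the other two replicates when each replicate was left out; promoter distances of 200 and 1000 bp; protein-coding TSSs only; the relaxed pooled peaks outside the IDR set as background; the gene of the nearest TSS only; windows of 25 and 100 bp each side; a flank at 500 bp; promoter peaks only; words of 6 bases; the search and test arms exchanged; a reciprocal overlap of 50%; replicate lists shortened to 4315 peaks; and peaks present in both replicates for the correlation. Added after the data were seen were 1 summit per interval, genes with 1 TSS position only, 10000 random lists matched on TSS number and head-to-head promoters, peaks outside promoters only, and each motif with its bases in reversed order.

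The overlap, promoter, gene list, word and motif steps were tested on simulated data. The promoter test on 8630 random summits gave no call in 19 of 20 runs and a call in 20 of 20 runs when 5% of the summits were moved to a TSS. On 13945 genes, lists of 20 to 40 members raised to 85% bound were called in 390 of 400 runs, lists lowered to 10% in 326 of 400, and 3583 of 3612 lists left at the background share were not called. Genes were drawn as bound independently of each other, so neighbours that share a summit were not covered. On 8630 peaks, a word planted in 10% of the windows was found in 10 of 10 runs, none was called in 10 of 10 runs without one, and 279 of 280 motif tests of flank against flank gave no call. These word and motif runs used flanks on both sides, so they do not cover calls caused by the lower GC content of the summits. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.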

Results

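Genomic occupancy of Zif (CG10267), a C2H2 zinc finger protein with a zinc finger-associated domain, was measured in whole mixed-sex Drosophila melanogaster embryos aged 0 to 24 h. The flies carried a transgene with GFP at the C-terminal end of Zif, and chromatin was precipitated with an anti-GFP antibody and sequenced (ChIP-seq). The 3 biological replicates formed 1 group, and the labels give no treatment or second genotype. The design therefore asks which regions the tagged protein occupied, at which genes and sequences they lie, and how far the replicates gave the same regions. The values are peak positions on dm6 and the peak caller's signal for each peak, which is taken to grow with the enrichment of the ChIP library over its control. No read counts accompany the peaks, so the sequencing depth of each replicate is unknown, and a region without a peak was not shown to be unoccupied.

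The final set of the authors held 8630 summits in 8135 intervals, selected by the irreproducible discovery rate (IDR), a measure of how well peaks rank alike in replicates. These IDR peaks had signals from 204 to 8172 with a median of 405, a median width of 390 bp, and covered 3.19 Mb. Their density was 68.3 summits per Mb on 2L, 62.8 on 2R, 66.1 on 3L, 61.4 on 3R, 66.0 on X and 38.6 on chromosome 4, where 52 summits lay. Each relaxed list, which keeps weak peaks, held 30000 summits, so that number was a limit on the list and not a count of occupied sites. The IDR set was the 8630 summits of highest signal in the pooled relaxed list, where 12941 of the 30000 summits had the maximum −log10 q value. A region outside the IDR set can therefore still hold a called peak, and genes given below as not bound were not shown to be unoccupied.

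The question of the replicate comparison is whether separate biological replicates gave the same regions in the same order. The strongest IDR peak, upstream of CG14100, ranked 1 in replicate 1, 4 in replicate 2 and 1 in replicate 3 among the IDR peaks. A relaxed peak of each of the 3 replicates overlapped 8477 of the 8630 IDR peaks (98.2%, 95% CI 97.9 to 98.5). The relaxed list of replicate 1 overlapped 8590 of them (99.5%). The labels name replicates 2 and 3 as sources of the pooled list and the IDR set, but the pooled signal was close to the sum over all 3 replicates (median ratio 0.991 at 7502 peaks, against 1.82 for replicates 2 and 3), so no replicate is taken here as independent of the set. The 8630 strongest peaks of a replicate covered 94.1% of the IDR peaks in replicate 1, 82.9% in replicate 2 and 89.1% in replicate 3. Among these equally long lists, 84.4% of the peaks of replicate 1 were shared with replicate 3 and 78.2% with replicate 2. Replicate 2 shared 87.1% with replicate 1 and 83.8% with replicate 3, and replicate 3 shared 90.5% with replicate 1 and 80.9% with replicate 2. Peaks placed at random shared 4.99% to 5.75%. Across the 8630 peaks, which are not independent replicates, Spearman's rho of the signal was 0.746 between replicates 1 and 2, 0.880 between replicates 1 and 3 and 0.719 between replicates 2 and 3. Replicate 2 stood apart in its balance of regions: the median signal at promoter peaks over that at other peaks was 2.18 in replicate 2 and 1.22 in each of replicates 1 and 3. A summit that shares its interval with a stronger one takes the stronger value in this comparison.

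**Figure D1:**
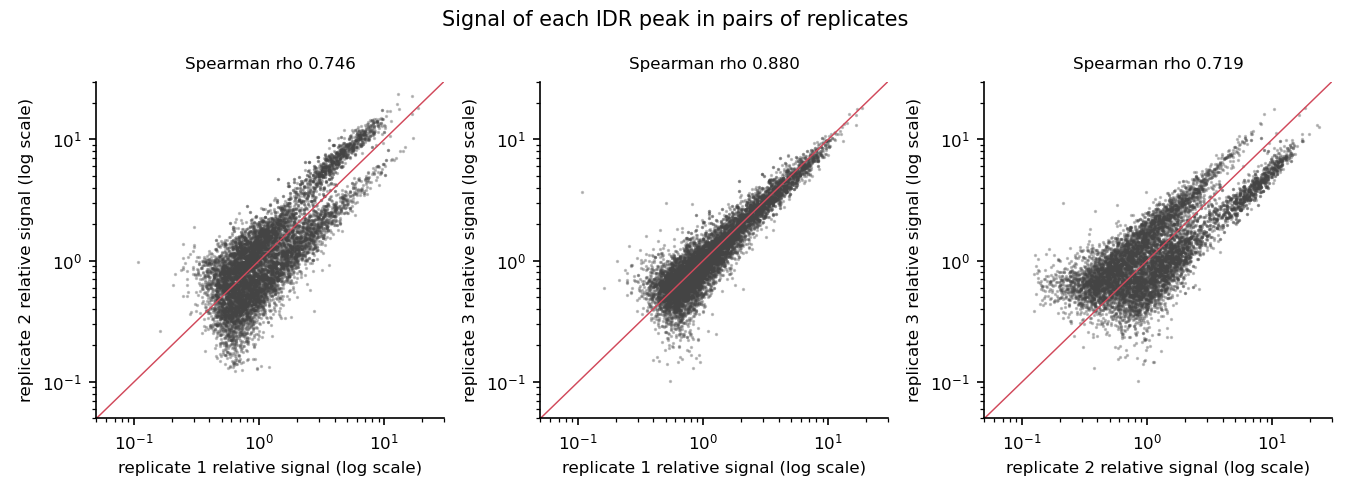
Signal of each of the 8630 IDR peaks in pairs of replicates, each axis showing the signal of a replicate divided by its median over the IDR peaks, on a log scale; points are peaks with a relaxed peak in both replicates and the line marks equal values. Replicates 1 and 3 lie along 1 band (Spearman's rho over all 8630 peaks 0.880), while both panels with replicate 2 show 2 bands (0.746 and 0.719).

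The strongest peaks lay mostly at promoters. The 25 strongest promoter peaks had signals of 4546 to 8172 and ranks of 1 to 28 among all IDR peaks, and 14 of them lay within 500 bp of the transcription start sites (TSSs) of 2 or more protein-coding genes. Relative signal below is the signal of a replicate divided by its median over the IDR peaks. The strongest peak (3L 19590257 to 19591052) had its summit at −112 bp from the TSS of CG14100, where negative values lie upstream, with a signal of 8172 and a relative signal of 18.3 ± 0.263 (SD, n = 3). The next (3L 8600508 to 8601352, signal 7594, relative signal 17.5 ± 4.86, SD, n = 3) lay at −63 bp from Nelf-E, which encodes a subunit of the negative elongation factor, and within reach of RpL14, a ribosomal protein gene. Peaks at CG11309 and CG7632 (signal 7276, relative signal 16.3 ± 0.329), px, named for extra wing veins in its mutants (6999, 15.0 ± 4.14), CG7379 (6855, 16.4 ± 6.29) and eIF2A, a translation initiation factor (6153, 14.4 ± 4.58), followed.

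Further peaks in this group lay at Vha55 and Snx3 (signal 5849), which encode a subunit of the vacuolar proton pump and a sorting nexin, at CG8892 and CG34126 (5528), at Phs (5455), at CG13919 and alphaCOP, a coat protein gene of secretory vesicles (5157), and at SRPK and dup, which encode a kinase of splicing factors and a replication licensing factor (5149). Fancm, a DNA repair helicase gene (4969), eIF4EHP and CG18428 (4959), CG18549 (4900), PIG-F and Lon, a mitochondrial protease gene (4789), NAT1 (4760) and Fkbp14 (4665) came next. The last 8 were the peaks at Polr2B and 140up (4658), tai and CG9586 (4632), mRpS10 and Art3 (4623), Ugalt (4609), mRpL23 and CG9004 (4587), sds22 and Brf (4569), CG8360 and CG8372 (4564), and dos (4546). Relative signals of the 25 peaks ran from 9.84 to 18.3. Every one ranked 53 or better in replicate 1 and 96 or better in replicate 3. In replicate 2, px ranked 182, CG18549 485, mRpS10 500, Fkbp14 502 and Ugalt 508.

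Of the 5 strongest peaks farther than 500 bp from any TSS, 3 lay in introns. The strongest, in an intron of ush, a gene for a GATA cofactor (2L 480534 to 481397, summit 481085, signal 6169, relative signal 13.1 ± 3.96, SD, n = 3), was 1397 bp from the nearest TSS, that of cbt. The others lay in an intron of CG11050 (signal 5610, 1022 bp from a TSS), between genes near DNAlig3 (5455, 1284 bp), between genes near RhoL (4249, 1574 bp) and in an intron of Lk6, a kinase gene (4174, 972 bp). In replicate 2 the 5 peaks ranked 301, 367, 357, 47 and 608 in this order, against 5, 6, 7, 51 and 26 in replicate 1.

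Zif has been described as acting on aPKC, the atypical protein kinase C of polarised neural stem cells, so both genes were examined whatever their values. The promoter of Zif itself carried an IDR peak (3R 6456364 to 6457602, summit 6457183) at 43 bp from its TSS, with a signal of 2708, rank 285 and a relative signal of 6.45 ± 2.12 (SD, n = 3). The promoter of aPKC carried one (2R 14962711 to 14963520, summit 14963078) at −109 bp, with a signal of 3339, rank 151 and a relative signal of 7.96 ± 2.67 (SD, n = 3). The aPKC summit also lay within 500 bp of the TSS of ckn, on the opposite strand, and the 2 genes cannot be separated by position. The labels do not say whether the transgene holds the Zif promoter, and reads from such a copy would be counted at the gene's own locus.

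**Figure D2:**
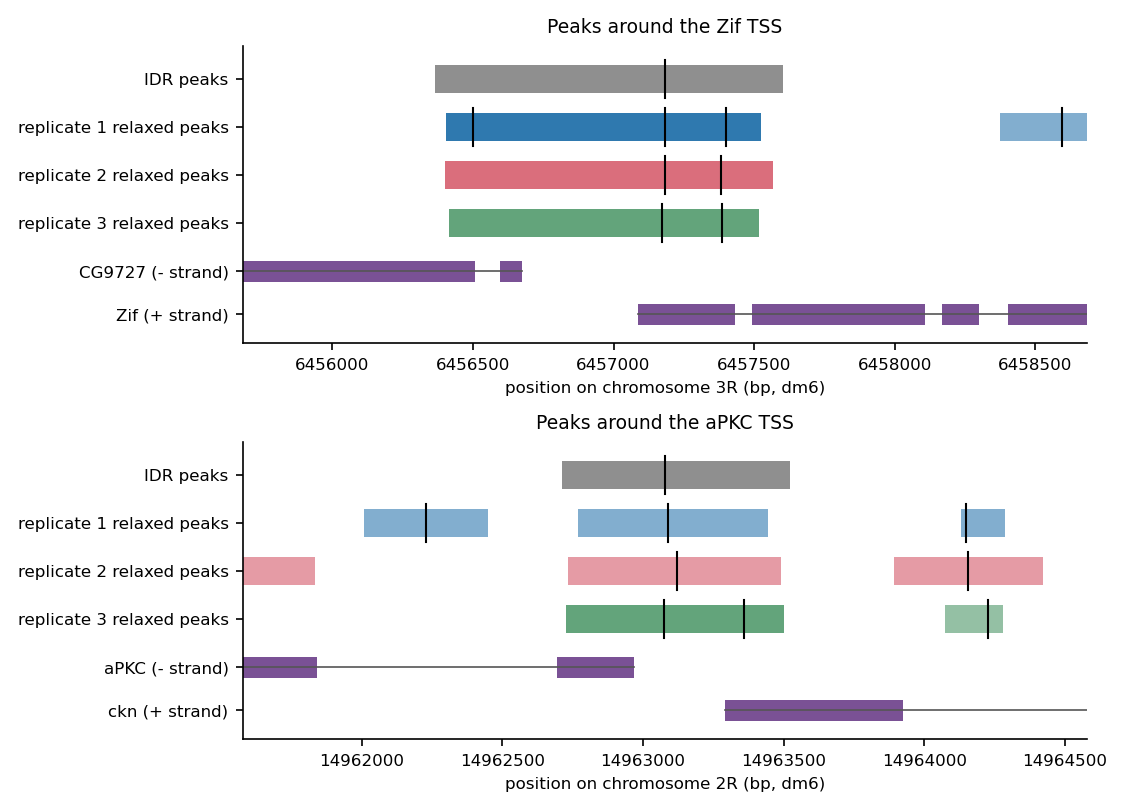
Peaks around the summits at the Zif and aPKC promoters on dm6 (horizontal axis in bp): the IDR set and the relaxed list of each replicate as bars with summits as black lines, darker where summits share an interval, and below them the exons of protein-coding genes. All 3 replicates have a relaxed peak over the summits at 6457183 (Zif) and 14963078 (aPKC).

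Where the tagged protein lay in the genome was compared with random placement. Promoters, within 500 bp of any annotated TSS, held 5152 of the 8630 summits (59.7%, 95% CI 58.7 to 60.7), against 13.6% of summits placed at random on the same chromosomes (range 12.4 to 14.7), a 4.39-fold excess. Introns held 2137 summits (24.8%, against 39.4% at random), intergenic sequence 1169 (13.5% against 27.2%), 3′ UTRs 68 (0.788% against 4.39%), 5′ UTRs 37 (0.429% against 0.769%) and other exons 54 (0.626% against 0.824%). Coding exons held 13 (0.151% against 13.8%). Near protein-coding TSSs, the median summit lay at −84 bp (interquartile range −161 to −24), and 4184 of 4948 (84.6%, 95% CI 83.5 to 85.6) lay at or upstream of the nearest TSS. A summit between 2 TSSs that point away from each other is upstream of both, and the share this layout alone would give was not computed. The promoter share gave p = 0.002 in the two-sided permutation test with 1000 placements, the smallest that number can give. Among 18851 relaxed pooled peaks outside the IDR set, 22.3% lay at promoters. The replicates' own 8630 strongest peaks gave 57.2%, 69.2% and 58.9% (mean 61.8% ± 6.51, SD, n = 3), with replicate 2 the highest.

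**Figure D3:**
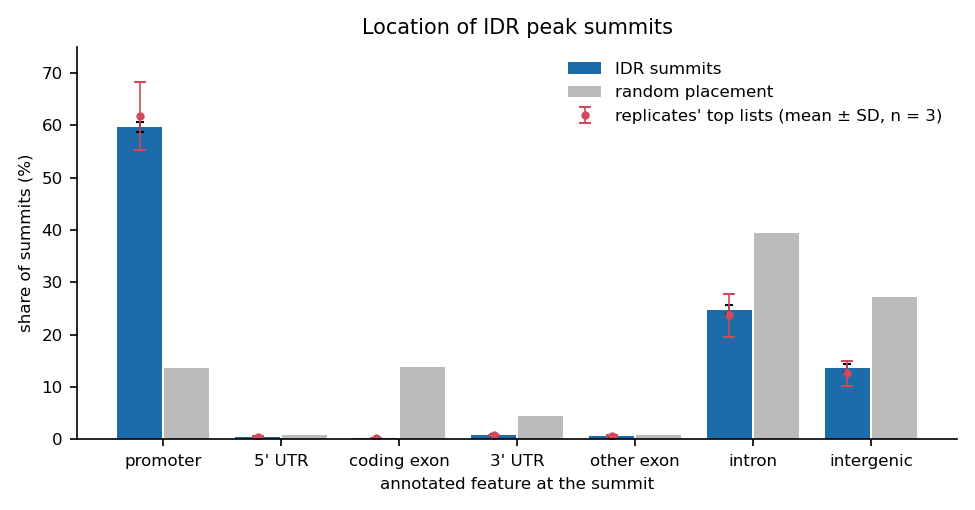
Share of summits in each annotated feature (percent): blue bars, the 8630 IDR summits with 95% binomial intervals; grey bars, random placement; red points, the mean ± SD of the 8630 strongest peaks of each of the 3 replicates. Promoters hold 59.7% of the IDR summits and 13.6% of the random ones.

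Of 13945 protein-coding genes, 5723 (41.0%, 95% CI 40.2 to 41.9) had an IDR summit within 500 bp of a TSS and are called bound here; the replicates' own lists gave 5626 ± 422 genes (SD, n = 3). The median signal of the bound genes' strongest peaks was 517. Where only numbers follow a gene name below, they are its signal and then its relative signal with the SD over 3 replicates. Of the 26 gene lists, 12 held more bound genes than the remaining genes, 7 held fewer, and 7 did not pass the threshold (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05 over the 26 lists).

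Genes that direct the asymmetric division of neural stem cells were mostly bound, 20 of 23 (87.0%, replicates 88.4% ± 9.05, SD, n = 3, Fisher's exact test, adjusted p = 3.24e-05). They included polo and aurA, mitotic kinase genes, with signals of 3757 and 3086 and relative signals of 8.83 ± 2.73 and 7.499 ± 3.45 (SD, n = 3), and stau, an RNA-binding protein gene (signal 2275, relative signal 5.44 ± 1.77). Cdc42, l(2)gl and pins were not bound. The list shares polo with that of cell cycle and replication genes, and its share was like the 84.2% of that list. The share therefore does not single out neural stem cells. Transcription factors and temporal factors of the same stem cells were mostly unbound, 2 of 23 (8.70%, replicates 13.04% ± 4.35, exact adjusted p = 0.00180). The bound pair were Imp, an RNA-binding protein gene (signal 992, relative signal 2.16 ± 0.329), and grh (531, 1.09 ± 0.452). That call was lost among the 4315 strongest peaks (8.70% against 26.03%, exact adjusted p = 0.0857).

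No marker list of a cell type or tissue held more bound genes than the remaining genes past the threshold. Bound members were 5 of 18 for neurons (27.8%, replicates 22.2% ± 0, exact adjusted p = 0.401), among them elav, a neuronal RNA-binding protein gene (signal 2789, relative signal 5.97 ± 1.75, SD, n = 3), 4 of 13 for glia (30.8%, 33.3% ± 4.44, exact adjusted p = 0.601), 5 of 19 for muscle (26.3%, 26.3% ± 0, exact adjusted p = 0.304), among them tin (1591), and 2 of 12 for trachea (16.7%, 22.2% ± 4.81, exact adjusted p = 0.181). They were 6 of 12 for gut (50%, 47.2% ± 12.7, exact adjusted p = 0.601) and 6 of 14 for germline (42.9%, 45.2% ± 8.25, exact adjusted p = 1), among them spn-E, a piRNA pathway gene (1765). The germline counts leave out nos, whose symbol had no match, so they do not describe the whole list as chosen. Hemocyte markers, 2 of 15 (13.3%, 11.1% ± 3.85, exact adjusted p = 0.0467), the list of epidermis and cuticle markers, 1 of 14 (7.14%, 9.52% ± 4.12, exact adjusted p = 0.0166), and segmentation and Hox genes, 6 of 32 (18.8%, 13.5% ± 1.80, exact adjusted p = 0.0166), fell below the remaining genes by Fisher's exact test. The bound member of the epidermis list, krz, encodes an arrestin and is not a marker of epidermis. The bound segmentation and Hox genes included bcd, the anterior morphogen gene (signal 637, relative signal 1.39 ± 0.213, SD, n = 3), and Dfd (434). With 10000 random lists matched on TSS number and head-to-head promoters, a comparison added after the data were seen, the adjusted permutation p was 0.106 for hemocytes and 0.219 for segmentation and Hox genes, so neither call held; epidermis kept its call there (0.0140) but lost it in 5 other settings (exact adjusted p from 0.0584 at 200 bp to 0.490 among genes with 1 TSS position). Hemocytes also lost the call without replicate 1 (exact adjusted p = 0.141), while neurons without replicate 3 (11.1% against 37.6%, exact adjusted p = 0.0333) and trachea at 200 bp (0% against 33.2%, exact adjusted p = 0.0168) passed as lower.

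Genes for chromatin organisation and the cell cycle were bound far more often than other genes. Polycomb and Trithorax group genes, which maintain repressed and active states, had 23 of 26 bound (88.5%, replicates 88.5% ± 6.66, SD, n = 3, Fisher's exact test, adjusted p = 2.35e-06). Examples were Snr1 (signal 3999, relative signal 9.35 ± 3.04), E(z) (3919, 8.99 ± 1.14), Su(z)12 (3785, 9.05 ± 3.31) and fs(1)h (3712, 8.61 ± 3.04); Psc, Sce and ash2 were not bound. Architectural and insulator proteins had 18 of 21 (85.7%, 84.1% ± 9.91, exact adjusted p = 0.000113), with Chro (signal 3981, relative signal 8.47 ± 1.92), Cp190 (2339, 5.08 ± 0.707), BEAF-32 (1912, 4.69 ± 1.59) and M1BP (1555, 3.50 ± 0.769), and without Nipped-B, ZIPIC and vtd. Cell cycle and replication genes had 32 of 38 (84.2%, 83.3% ± 7.60, exact adjusted p = 2.05e-07). They included dup (signal 5149, relative signal 12.2 ± 4.45), Orc1 of the origin recognition complex (3666, 8.77 ± 3.70) and dpa of the replicative helicase (3256, 7.69 ± 2.73), while Cdk2, CycE, Mcm3, Mcm7, Psf2 and stg were not bound.

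Genes for protein synthesis, RNA processing and transcription were also bound more often than other genes. Cytosolic ribosomal protein genes had 83 of 92 bound (90.2%, replicates 90.9% ± 2.26, SD, n = 3, Fisher's exact test, adjusted p = 6.11e-22), with RpL14 (signal 7594), RpL23A (4359) and RpS27 (4134, relative signal 9.78 ± 2.85). Mitochondrial ribosomal protein genes had 61 of 73 (83.6%, 84.5% ± 7.54, exact adjusted p = 5.39e-13), with mRpS10 (4623, 9.84 ± 2.59) and mRpL23 (4587, 10.4 ± 0.949). Spliceosome components had 26 of 32 (81.3%, 80.2% ± 9.02, exact adjusted p = 1.41e-05), with U2af50 the strongest at 1139 (2.49 ± 0.279). General transcription machinery had 60 of 80 (75%, 75.8% ± 10.6, exact adjusted p = 3.33e-09), with the RNA polymerase subunit genes Polr2B (4658, 10.99 ± 3.17) and Polr2F (4258, 10.02 ± 2.79) and the Mediator gene MED17 (4014, 9.66 ± 3.37). Translation initiation factors had 29 of 44 (65.9%, 66.7% ± 5.72, exact adjusted p = 0.00180), with eIF2A (6153) and eIF4EHP (4959, 11.04 ± 0.312). Proteasome subunits had 32 of 48 (66.7%, 62.5% ± 9.08, exact adjusted p = 0.000787), with Rpn2 (3794, 8.97 ± 3.18), aminoacyl tRNA synthetases 21 of 32 (65.6%, 69.8% ± 10.05, exact adjusted p = 0.0101), with GlyRS (3598, 8.61 ± 3.49), and oxidative phosphorylation subunits 52 of 87 (59.8%, 59.8% ± 6.08, exact adjusted p = 0.000870), with COX5B (3191, 7.495 ± 2.46). The proteasome and oxidative phosphorylation lists also hold paralogs of the subunit genes. Their unbound members included Prosalpha4T1, Prosbeta2R1, COX4L and SdhAL, beside Prosalpha1, Rpt3 and ND-30, so these shares are not of the main subunits alone. Against the matched random lists the tRNA synthetases (permutation adjusted p = 0.4996) and oxidative phosphorylation subunits (0.106) no longer passed. A summit near the TSSs of 2 genes counts for both, which raises some shares. The matched lists had 60.3% bound for mitochondrial ribosomal proteins and 55.2% for general transcription machinery, which both kept their calls. With the gene of the nearest TSS only, their shares were 52.1% and 50%, each against 31.3% (exact adjusted p = 0.000926 and 0.0015). The proteasome call was lost without replicate 2 (47.9% against 35.0%, exact adjusted p = 0.0944) and among the 4315 strongest peaks (0.182), and that of the initiation factors among genes with 1 TSS position, also added later (51.7% against 35.1%, exact adjusted p = 0.113).

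Genes of the chemoreceptor, cuticle protein and histone lists were rarely bound. The chemoreceptor list had 7 of 230 bound (3.04%, replicates 2.46% ± 0.905, SD, n = 3, Fisher's exact test, adjusted p = 1.25e-40), with Gr63a, a carbon dioxide receptor gene, the strongest (signal 2589), and cuticle protein genes had 3 of 117 (2.56%, 1.71% ± 0.855, exact adjusted p = 1.04e-21), with Lcp9 the strongest (1784). The chemoreceptor list also holds odorant-binding protein genes, which do not encode receptors, Obp93a and Obp99b among the bound ones. Heat shock protein genes had 6 of 19 (31.6%, 31.6% ± 0, exact adjusted p = 0.552), with Hsp83, a chaperone gene, the strongest (3636, 8.43 ± 1.64). Among genes with 1 TSS position they passed as lower (7.14%, exact adjusted p = 0.0454). None of the 68 replication-dependent histone genes was bound (0%, 95% CI 0 to 5.28, 0% in each replicate, exact adjusted p = 1.82e-15). Those genes are near-identical copies in a cluster (2L 21416953 to 21541153) that held 0 relaxed summits of the pooled list and 0 of replicate 1. Reads from near-identical copies cannot be assigned to a single copy, so this value is uncertain.

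**Figure D4:**
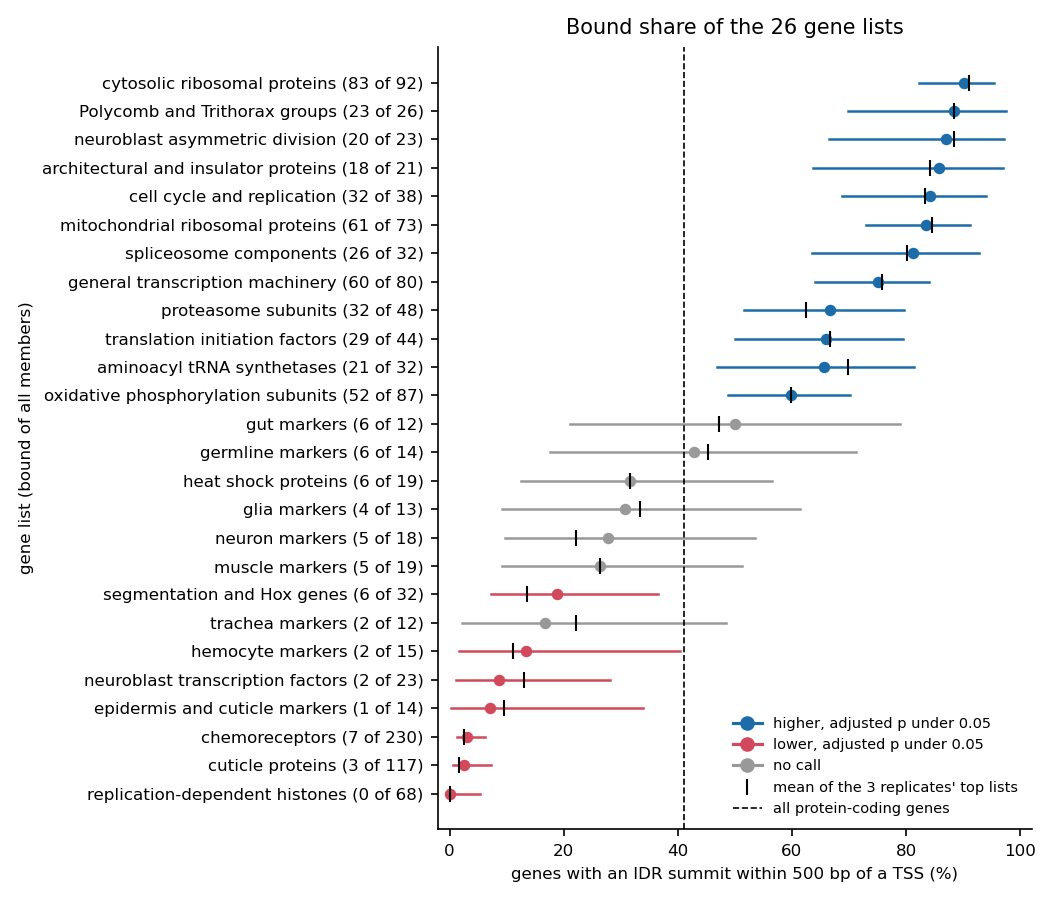
Share of bound genes in each of the 26 gene lists (percent, points with 95% binomial intervals), coloured by the outcome of Fisher's exact test after adjustment; black ticks, the mean of the 3 replicates' own lists; dashed line, all protein-coding genes (41.0%). The lists run from cytosolic ribosomal proteins (90.2%) to replication-dependent histones (0%).

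Promoter architecture separated bound from unbound genes. Of 3815 genes with a head-to-head neighbour, whose TSS lies on the opposite strand within 500 bp upstream, 2948 were bound (77.3%, 95% CI 75.9 to 78.6, replicates 76.1% ± 6.002, SD, n = 3). Of the other 10130 genes, 2775 were bound (27.4%, 95% CI 26.5 to 28.3, 26.9% ± 1.93). The odds ratio was 9.01, with a p from Fisher's exact test too small for the software to represent. A summit between 2 such TSSs counts for both genes: with the gene of the nearest TSS only, the odds ratio was 2.38 (Fisher's exact test, p = 8.57e-105).

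The embryos were of both sexes, and the X chromosome was compared with chromosomes 2 and 3. On X, 941 of 2196 genes were bound (42.9%, replicates 41.1% ± 4.12, SD, n = 3), against 4752 of 11669 (40.7%, 40.2% ± 2.82) on the autosomes, an odds ratio of 1.09 that did not pass (two-sided Fisher's exact test, p = 0.0652). Among the 4315 strongest peaks the direction turned, with 23.3% bound on X and 26.6% on the autosomes (odds ratio 0.836, p = 0.001), and with a promoter distance of 1000 bp the excess on X passed (1.12, p = 0.0160, Fisher's exact tests). With any 1 replicate left out the odds ratio was 0.937 to 0.9997.

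Sequences known from fly promoters were compared between a window of 50 bp each side of each summit and an equal window 300 bp away beside the same peak. Of 14 motifs, 8 were more frequent at the summits, 5 were less frequent and 1 did not pass. The DNA replication-related element TATCGATA, bound by Dref, lay at 4.24% of the summits and 0.649% of the flanks (6.536-fold, exact McNemar test, adjusted p = 2.05e-57, replicates 4.31% ± 0.770, SD, n = 3). The BEAF-32 core CGATA lay at 21.1% against 12.0% (exact adjusted p = 3.58e-58), and Motif 1, bound by M1BP, at 1.54% against 0.209% (exact adjusted p = 2.05e-22). CGATA is part of TATCGATA, so the 366 summits with the DNA replication-related element are all among the 1824 with CGATA. The calls of these 2 motifs are therefore not separate. The Su(Hw) core was at 0.927% against 0.463% (exact adjusted p = 0.000421). With the bases of each motif in reversed order, a control of base composition added after the data were seen, Motif 1 was at 0.313% against 0.0348% and Su(Hw) at 0.232% against 0.0927%, ratios no smaller than those of the motifs themselves. Reversed Motif 1 holds ACACTG, which is also part of the word CAACACTG found below. For Motif 1 the reversed order is therefore not a control of composition alone, and its result decides nothing. Reversed, the DNA replication-related element was at 0.348% against 0.174% and CGATA at 16.6% against 12.2%. Lower at the summits were the GAGA element (0.9502% against 2.48%, exact adjusted p = 1.21e-14), CA repeats (0.684% against 3.75%, exact adjusted p = 1.93e-45), the TCT initiator of ribosomal protein genes (9.14% against 11.8%, exact adjusted p = 2.79e-08) and the Zelda site (0.313% against 0.591%, exact adjusted p = 0.0102). Reversed, CA repeats (0.823% against 3.43%), TCT (8.90% against 11.02%) and Zelda (0.614% against 0.765%) were lower too, while GAGA reads the same reversed. The CTCF core was at 3.56% against 4.30% (exact adjusted p = 0.0155), and reversed at 0.985% against 3.22%. Its direction turned without replicate 1 (3.69% against 3.53%, exact adjusted p = 0.672), and its call was lost in 5 other settings, among them the 4315 strongest peaks (exact adjusted p = 0.207) and promoter peaks only (0.797). The E-box CAGCTG did not pass over all peaks (5.04% against 4.83%, exact adjusted p = 0.5503), but was higher at promoter summits (7.12% against 5.03%, exact adjusted p = 2.08e-05) and lower at the others (1.96% against 4.43%, exact adjusted p = 8.11e-09). It also passed as higher without replicate 3 (5.64% against 4.68%, exact adjusted p = 0.0152).

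Base composition moved with these counts. The GC content was 33.3% at the summits and 43.8% in the flanks, with 35.3% against 43.6% at promoter peaks and 30.3% against 44.3% at the others. The TATA box (9.47% against 3.87%, exact adjusted p = 5.22e-49), GATA (21.2% against 15.7%, exact adjusted p = 4.98e-20), initiator (25.4% against 21.7%, exact adjusted p = 2.79e-08) and downstream promoter element (53.5% against 50.3%, exact adjusted p = 6.02e-05) were higher at summits by the same exact test. The same bases in reversed order were higher too for TATA (15.5% against 6.04%), GATA (26.3% against 14.4%) and the initiator (21.2% against 16.05%), while the downstream element reversed was at 59.5% against 59.3% and the E-box at 0.568% against 1.55%. At peaks outside promoters, CGATA was at 10.1% against 11.4% (exact adjusted p = 0.0864), and with the flank at 500 bp the downstream element was at 53.5% against 53.6%.

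A search for enriched words on 2L, 2R and X found ATCGATAG, which overlaps the DNA replication-related element. The matrix grown from it matched 503 of 3829 summits on the held-out arms 3L and 3R (13.1%, 95% CI 12.1 to 14.2), against 4.36% of the flanks (exact McNemar test, p = 9.62e-44). The word found depended on the setting: with the search and test arms exchanged it was TTAAAAAA, whose matrix matched 17.4% of the summits against 5.87% of the flanks, without replicate 2 it was TTTAAAAA and with words of 6 bases AAATAT, all A and T at summits low in GC. Held-out peaks with a match had a median signal of 411 and those without one 413, a ratio of 0.994 (two-sided permutation test, p = 0.844). At promoter peaks only, where the search found the same word, peaks with a match had the lower signal and the difference passed (0.879, permutation p = 0.0141). For the matrices found with a replicate left out, which differ, the ratio was 1.21 without replicate 1 (TATCGATA, permutation p = 1e-05, the smallest the test can give), 1.12 without replicate 2 (TTTAAAAA, permutation p = 0.00460) and 0.851 without replicate 3 (ATCGATAG, permutation p = 0.00140). Among the 4315 strongest peaks the search found another word, CAACACTG, whose matrix matched 15.1% of 1964 held-out summits against 4.38% of the flanks (exact McNemar test, p = 1.3e-29). Held-out peaks with that match had a median signal of 1412 and those without one 667, a ratio of 2.12 (two-sided permutation test, p = 1e-05, the smallest the test can give).

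The frequency of CAACACTG by peak signal was examined after this result was seen. In 10 equal bins of 863 peaks, the word lay at 1.04% of the summits of the weakest bin, 4.98% of bin 9 and 17.5% of the strongest bin (151 peaks, 95% CI 15.0 to 20.2), where 0.579% of the flanks held it. The DNA replication-related element did not rise steadily with signal, at 4.06% of the weakest bin, 2.32% of bin 9, the lowest of all, and 6.26% of the strongest bin. The promoter share was 48.0% in the weakest and 84.7% in the strongest bin. Of the 25 strongest promoter peaks, 7 matched the matrix and 3 of them held the word itself, those at eIF2A, Phs, and SRPK with dup. The peaks at Zif and aPKC, both in the strongest bin, matched too. In that bin 37.3% of the peaks on the held-out arms matched. Zif lies on 3R, which was held out, but aPKC lies on 2R, on which the matrix was grown. These matches therefore say little about the 2 genes in particular.

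**Figure D5:**
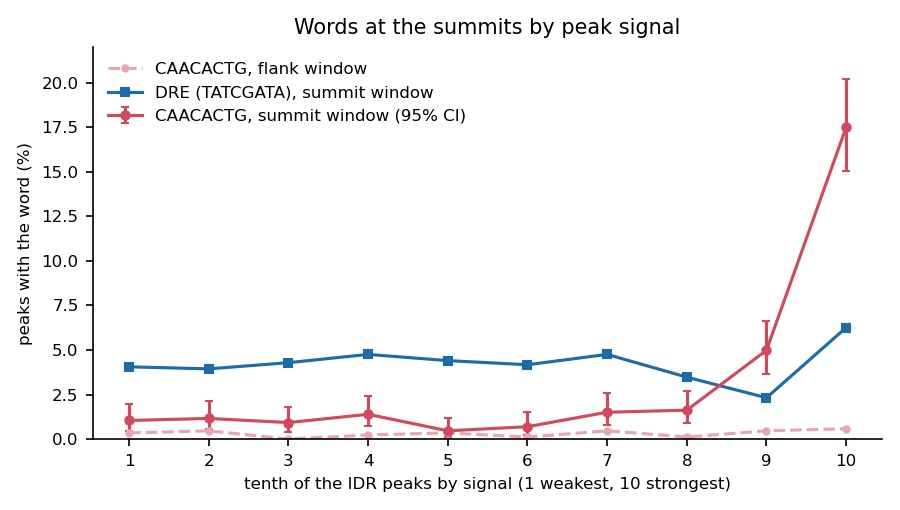
Share of IDR peaks with a word within 50 bp of the summit (percent), in 10 equal bins of peaks by signal from weakest (1) to strongest (10): CAACACTG at the summits with 95% binomial intervals, CAACACTG in the flank windows, and the DNA replication-related element TATCGATA at the summits. CAACACTG lies at 17.5% of the summits of the strongest bin and 1.04% of the weakest.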

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

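Chosen only after the data were seen were the tests with 1 summit per interval, genes with 1 TSS position, matched random lists, peaks outside promoters and reversed motifs. The promoter share kept its direction and its call under every alternative, from 47.3% (200 bp) to 68.6% (without replicate 1), as did head-to-head promoters, with odds ratios of 2.38 to 9.74. Of 234 results for single lists under the alternatives other than the matched random lists, 205 kept direction and call, 16 lost the call, 3 gained one and 10 turned direction. Against the matched random lists 15 lists passed, and hemocytes, segmentation and Hox genes, tRNA synthetases and oxidative phosphorylation lost the call. For motifs, 122 of 140 results kept both, 7 lost the call, 2 gained one and 9 turned. The number of lists past the threshold was 15 to 20, against 19. The cause was not tested for any change below, except that shorter or stricter lists hold fewer peaks.

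With 50% reciprocal overlap, the share of replicate 1 peaks found was 59.5% in replicate 2 and 68.8% in replicate 3, that of replicate 2 peaks 64.66% in replicate 1 and 64.67% in replicate 3, and that of replicate 3 peaks 73.0% in replicate 1 and 63.2% in replicate 2. With lists of 4315 peaks, the shares were 73.95% (1 in 2), 81.3% (2 in 1), 76.8% (2 in 3), 89.5% (3 in 1) and 74.8% (3 in 2). None of the list results that turned passed the threshold in that setting. Gut markers were at 25% with the 4315 strongest peaks and at 200 bp, 0% among genes with 1 TSS position, and 25% to 41.7% with a replicate left out, below the other genes without replicate 1 (33.3%) or 2 (25%). Germline markers were at 35.7% to 50% with a replicate left out, turning without replicate 3 (35.7%). Heat shock genes were at 31.6% with the 4315 strongest peaks and with the nearest TSS, glia markers at 46.2% at 1000 bp, and neuron markers at 40% among genes with 1 TSS position.

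List calls were lost with the 4315 strongest peaks for neuroblast transcription factors (exact adjusted p = 0.0857, and so for the values below), epidermis (0.182) and the proteasome (0.182), for epidermis at 200 bp (0.0584) and 1000 bp (0.139), and with the nearest TSS for hemocytes (0.244), epidermis (0.128), segmentation and Hox genes (0.202) and tRNA synthetases (0.247). Among genes with 1 TSS position they were lost for hemocytes (0.136), epidermis (0.490), segmentation and Hox genes (0.0726), initiation factors (0.113) and oxidative phosphorylation (0.0887), without replicate 1 for hemocytes (0.141) and without replicate 2 for the proteasome (0.0944). Calls as lower were gained by neurons without replicate 3 (0.0333), trachea at 200 bp (0.0168) and heat shock genes with 1 TSS position (0.0454). Motif calls were lost for the CTCF core with the 4315 strongest peaks (0.207), windows of 25 bp (0.310), the flank at 500 bp (0.217), promoter peaks (0.797) and without replicate 3 (0.928), and for Zelda with windows of 25 bp (0.126) and outside promoters (0.150). The E-box gained calls as higher at promoters (2.08e-05) and without replicate 3 (0.0152).

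The odds ratio of X against autosomes was 0.836 with the 4315 strongest peaks, 1.12 at 1000 bp, and 0.937 to 0.9997 with a replicate left out. The E-box was at 5.26% with the 4315 strongest peaks, 5.04% with peaks of at least 2 replicates and with the flank at 500 bp, 1.96% outside promoters, and 4.64% to 5.64% with a replicate left out, passing as higher without replicate 3 (5.64%). The downstream promoter element was at 53.5% with the flank at 500 bp and 52.4% at promoters, CGATA at 10.1% outside promoters, and the CTCF core at 3.31% to 3.75% with a replicate left out, without its call when replicate 1 (3.69%) or 3 (3.75%) was left out. The signal ratio of peaks with and without the de novo match was 2.12 with the 4315 strongest peaks, 1.04 with peaks of at least 2 replicates, 0.879 at promoters (permutation p = 0.0141), and 0.851 (without replicate 3) to 1.21 (without replicate 1) with a replicate left out; the search found CAACACTG, TATCGATA, ATCGATAG, ATCGATAG and TATCGATA in these 5 settings, so the matrices differ. Depth is unknown, so which weak regions were missed in each replicate cannot be given.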

Other observations

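All tests in this section concern patterns found in these data and were chosen after the main results were seen. What each explanation predicts was written before its test was run, with 3 exceptions. These were the lowest signal ratio over the replicates, GC content as the whole cause of the replicate 2 pattern, and the matrix match in replicate 2. The test of the matrix match within gene lists had no written prediction. Among the 5723 bound genes, 1137 (19.9%) had a peak that matched the CAACACTG matrix of the strongest peaks. Cell cycle and replication genes held the match more often than other bound genes, 14 of 32 (43.8% against 19.7%; Fisher's exact test, p = 0.00260, adjusted p = 0.0492), and 1 of the 19 lists tested passed. The matrix was grown on 2L, 2R and X, and on the held-out arms 3L and 3R the count was 4 of 9 (44.4% against 18.9%; Fisher's exact test, p = 0.0720, adjusted p = 0.504), which did not pass with these fewer genes, at an odds ratio of 3.44 against 3.16 over all arms. The 14 were dup, geminin and Cdc6, which control replication licensing, E2f1, E2f2, Dp and Rbf of the E2F pathway, Orc1, Orc5 and dpa of replication origins, and polo, BubR1, CycA and Cdk4. Asymmetric division genes held the match at 8 of 20 (40%, Fisher's exact test, adjusted p = 0.270), aPKC, polo and stau among them, and bound genes of the chemoreceptor list at 4 of 7 (57.1%, adjusted p = 0.270), which did not pass.

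CAACACTG lay at 17.5% of the summits of the strongest bin of peaks. Base composition of the summits would give rearranged words of the same bases a like share, but their median was 0 of the word's share (0%, highest 1.02%, against 15.5% on 3L and 3R). A word common to any promoter would appear at the same distances from TSSs of genes without even a relaxed pooled peak nearby. It lay at 0.238% there against 20.2% at promoter peaks of the strongest bin, a ratio of 0.0118. The 20.2% covers all arms, also those on which the word was found. Genes were not matched on activity, so a word shared by active promoters stays open. If 1 library decided the pattern, the others would show no difference, but held-out peaks with a match had 1.69, 2.22 and 1.73 times the signal of those without in replicates 1, 2 and 3, each from its own list. Promoter copies of the word lay within 100 bp of a summit at 42.4% of 321 sites against 5.004% for rearranged words, a ratio of 8.47, and copies elsewhere at 2.44% of 1313 sites against 0.424%, but the word was found by its frequency at summits, so these shares restate the pattern and decide nothing on recruitment. Whether the tagged protein or a partner is recruited by the word therefore stays open, and no biological explanation was tested between groups, since the design has 1 group.

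GC content fell from 43.8% in the flanks to 33.3% at the summits. The composition of any promoter would give the same value at the same distances from TSSs of genes without even a relaxed pooled peak nearby. There it was 5.48 percentage points higher (40.9% against 35.5%), though the genes were not matched on activity. Nor did the weakest peaks carry the dip: outside promoters, it was 1.296 times as deep in the strongest as in the weakest 20% of the peaks by signal (−16.1 against −12.5 points). A GC bias of the libraries could also shape the dip and stays open, since the control library was not analysed here; no biological explanation was tested between groups.

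Replicate 2 ranked promoter peaks above other peaks more than replicates 1 and 3 did. A lower enrichment of weak peaks of every kind would vanish at matched signal, but at matched signal of replicates 1 and 3 promoter peaks still had 2.07 times the replicate 2 signal of other peaks (1.63 to 2.60 in the 10 bins). GC content may contribute, since among peaks outside promoters the GC-richer ones had 1.105 times the replicate 2 signal of the GC-poorer ones (0.910 to 1.58, above 1 in 9 of 10 bins), but it is not the whole cause, as the ratio of promoter peaks to others was 1.79 with signal and GC content both matched (1.301 to 3.27 over 25 cells). Among promoter peaks at matched signal, those with the CAACACTG matrix match had 1.18 times the replicate 2 signal of those without (0.984 to 2.01, above 1 in 9 of 10 bins), so replicate 2 may have enriched peaks without a match less. Differences in embryo age or handling stay open and were not tested, and no biological explanation was tested between groups.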
